A study of Escherichia coli and Escherichia coli K-12 with 3 samples.

How the data were processed

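RNA sequencing libraries of *Escherichia coli* BW25113 were analysed, 1 from growth without drug and 2 from growth with 12.5 µg/mL ciclopirox. Per the labels' protocols, RNA was stabilised at an optical density (OD600) of 1.0 and libraries were made with the Illumina TruSeq RNA kit, and the series was sequenced on a HiSeq 2500. The aligner, the counting program, the genome build, the annotation and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and near-identical pairs such as gadA with gadB and tufA with tufB are uncertain.

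The deposited table held 1 value per gene and library for 4290 genes named by b-number, with the authors' coordinates on a single contig. These signal values were gene counts that the authors had divided by 1 factor per library before deposit, as read from the values themselves: within each column every value was a whole multiple of 1 step, 100% of them within 0.1 of a whole read. The steps were 0.706 for the control, 1.36 for ciclopirox replicate 1 and 1.06 for replicate 2, and the median gene ratio to the control was close to 1, as median-of-ratios scaling gives. No division by gene length was seen. The table also held the authors' ratio of each ciclopirox library to the control and the mean of the 2 ratios. In the authors' deposited table these fold values equalled the quotients of the value columns within 1e-06 for all 4288 genes that had one, the other 2 genes being at 0 in the control. They were used only for that check. Gene symbols came from the RefSeq table of assembly ASM584v2, which matched 4283 of the b-numbers and left 7 unmatched, and none of its coordinates are given.

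Samples were grouped by the labels, and the treated samples carry replicate numbers 1 and 2. The recovered depth was 21213704 reads in the control, 8958322 in ciclopirox replicate 1 and 11990036 in replicate 2, so 1 read was worth 0.706, 1.36 and 1.06 normalised reads. A floor of 3 reads stands for a library with 0 reads, and 95% intervals of low-count ratios were exact for counts. Both cover counting error only.

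Because the table held normalised values, the test fixed for that case before the data were examined was used: limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, on log2(value + 1). Genes needed a mean of at least 1 over the 3 libraries, which left 4275 and removed 15, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 1 residual degree of freedom, from the ciclopirox libraries, and 9.03 prior degrees of freedom, so it rests mainly on the spread shared by all genes. Fold changes on this scale understate the change of low genes. Named genes were the 12 that rose and the 12 that fell most, ranked by the smaller in size of the per-library log2 ratios, among called genes with a higher group mean of at least 10. For each gene list, up to 4 members with the largest such ratio in the list's direction were named, with any member called the opposite way. Genes named outside this rule are said to be.

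A total of 41 gene lists, written before the data were examined, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The lists covered iron, manganese, zinc and copper handling, respiration and energy, oxidative and other stress responses, envelope and motility, translation, nucleotide and amino acid synthesis, and carbon use, with the genes deleted in the parent strain as a background list. The test was repeated with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way and called none, with a lowest false discovery rate of 0.189. Both repeats rest on the 1 residual degree of freedom and had little power, so a list that they left uncalled is undecided. The plan did not name fry. Counts adjusted over each list alone were also made. As planned, each list's median was set beside 10000 random lists matched on mean expression. That treats members as independent, so its percentiles can be too extreme. Among lists that camera did not call, the most extreme were fatty acid (0.69), terminal oxidases (1.8), ferrous iron import (3.57) and phage shock (99.69). Replicate agreement was set beside 100 simulated pairs of unchanged libraries that shared the control.

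The procedure was tested on simulated counts for the ciclopirox against control comparison, with 4262 genes tested by limma and 50 genes changed at each fold size. limma recovered 8% of 4-fold changes, 90% of 16-fold changes and 100% of 64-fold and of 256-fold changes, with 5 false calls among 154, and made 0 calls when nothing was changed. DESeq2 made 19 false calls among 164, and 5 calls when nothing was changed. All simulated genes shared a dispersion of 0.221, with no separate value for the control. Genes that differ in dispersion, or a control that varies unlike the ciclopirox libraries, were therefore not tested. These false-call counts hold for the simulated case and give no error rate for the calls in the real data. For lists of 20 genes shifted 4-fold, camera with the preset correlation called 4 of 4 shifted lists and 0 of 36 others, whereas with an estimated correlation it called 0 of 4. The simulated genes varied independently and the lists were drawn at random. The simulation therefore does not test the preset correlation for genes that are regulated together, where camera p-values can be too small.

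The alternatives planned before the data were examined were median-ratio rescaling, quantile normalisation, no low-value filter, a minimum mean of 10, pseudocounts of 0.1 and 5, limma without the trend or with robust moderation, and leaving out each ciclopirox replicate. Chosen after seeing the data were total-count scaling, edgeR 4.0.16 (quasi-likelihood test with trimmed-mean scaling) and DESeq2 1.42.0, the last 2 on the recovered whole reads. edgeR tested 4128 genes and called 422 higher and 326 lower, and 478 of limma's 486 calls were shared.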

Results

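RNA sequencing measured mRNA levels in *Escherichia coli* BW25113, a K-12 laboratory strain, grown in LB medium at 37 °C to an optical density (OD600) of 1.0. One culture condition had no drug and the other had 12.5 µg/mL ciclopirox, a hydroxypyridone antifungal known to chelate iron and other metal ions. The data comprised 1 control library and 2 ciclopirox libraries. The control library held 21213704 reads in genes, ciclopirox replicate 1 held 8958322 and ciclopirox replicate 2 held 11990036. Between 4265 and 4288 of the 4290 genes had at least 1 read in a library. The gene with the most reads, without regard to gene length, was fusA in the control (2.97% of reads). It was dps in ciclopirox replicate 1 (7.32%) and ompA in ciclopirox replicate 2 (3.03%). Values below are normalised read counts, the authors' gene counts divided by 1 factor per library, and fold changes are on the log2(value + 1) scale. The labels do not say whether the ciclopirox samples came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

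The comparison asked how a sublethal concentration of ciclopirox changes the mRNA profile. Called higher with the drug were 14 of 18 genes in the acid resistance list, 21 of 25 in the general stress list and 6 of 6 in the Suf iron-sulfur cluster assembly list. In the list of manganese import and the manganese-dependent ribonucleotide reductase 6 of 8 were called higher. The lists of ribosomal proteins, flagella and chemotaxis, and nucleotide synthesis were called downward with a preset correlation (7 of 54, 21 of 47 and 8 of 25 members lower), though no list was with an estimated correlation (adjusted p = 0.965). With 1 residual degree of freedom the test with an estimated correlation could not decide. The glutamate decarboxylase gene gadB rose 1908-fold, from 103 in the control to 198710 ± 9556 (SD, n = 2) with ciclopirox. The nickel-binding protein gene nikA fell from 2389 to 31.9 ± 8.74 (SD, n = 2), a 73.9-fold change. By limma, 302 genes were higher and 184 lower at an adjusted p under 0.05, and 3789 of the 4275 genes tested were not called.

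Most of the 12 genes that rose most belonged to the acid resistance list. They were gadB (b1493), gadC (b1492), gadA (b3517), slp (b3506), gadE (b3512), hdeB (b3509), hdeD (b3511), hdeA (b3510) and dctR (b3507). The last, a regulator gene, lies next to slp. The glutamate decarboxylase gene gadB lay at 1564902 to 1566302 on the minus strand of the single contig in the authors' table, whose genome build is not given in the sources used here. Its log2 fold change was 10.90 ± 1.25 (SE; limma adjusted p = 0.00147). The neighbouring glutamate antiporter gene gadC, at 1563211 to 1564746 on the minus strand, rose from 117 to 193000 ± 41617 (SD, n = 2), with a log2 fold change of 10.66 ± 1.26 (limma adjusted p = 0.0015). The second decarboxylase gene, gadA, at 3659540 to 3660940 on the minus strand, had a log2 fold change of 10.48 ± 1.24. The sequences of gadA and gadB are nearly identical, and how reads were shared between them is not stated, so their separate values are uncertain. The acid-resistance activator gene gadE rose to 10577 and 28297 in ciclopirox replicates 1 and 2, with log2 ratios of 8.16 and 9.58. The periplasmic acid chaperone genes hdeA and hdeB rose 333-fold and 418-fold, the membrane protein gene hdeD 281-fold and the outer membrane lipoprotein gene slp 534-fold. For dctR the control had 3 reads against 700 and 753, and the ratio of control to treated was 0.00223 (95% counting interval 0.000459 to 0.00655) in replicate 1 and 0.00266 (0.000547 to 0.00780) in replicate 2.

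The other 3 of the 12 were astC (b1748), astA (b1747) and glsA (b0485). The first 2 encode enzymes of the arginine succinyltransferase pathway, which breaks down arginine. The astC gene, at 1825019 to 1826239 on the minus strand, rose from 33.9 to 25447 ± 7433 (SD, n = 2), with a log2 fold change of 9.48 ± 0.95 (limma adjusted p = 0.00106). The adjacent astA gene, at 1823988 to 1825022, rose from 16.2 to 14513 and 5683. The glutaminase gene glsA, at 507097 to 508029 on the plus strand, rose 398-fold.

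Among the 12 genes that fell most, napF (b2208), napD (b2207) and nirB (b3365) belong to nitrate and nitrite reduction. The napF gene, at 2296482 to 2296976 on the minus strand, fell from 3052 to 14.9 and 1.06. Its 1 read in ciclopirox replicate 2, against 4323 in the control, gave a ratio of control to treated of 2883 (95% counting interval 517 to 113900). The overlapping napD gene, at 2296229 to 2296492, had 1 and 3 reads against 914, with ratios of 476 (85.2 to 18830) and 203 (69.3 to 987). The nitrite reductase gene nirB fell 59.2-fold, from 12507 to 282 and 157. The prophage genes borD (b0557) and rzpD (b0556) fell 199.7-fold and 52.4-fold. A further prophage gene, ydfO (b1549), had 57 reads in the control and 0 in both ciclopirox libraries. Against a floor of 3 reads per library it was at least 9.90-fold lower in replicate 1 and at least 12.7-fold lower in replicate 2, and the lower ends of the 95% counting intervals were 7.79 and 9.97. The others were transport and metabolic genes: nikA (b3476), the asparaginase gene ansB (b2957), the putrescine importer gene plaP (b2014), the uracil permease gene uraA (b2497), the ubiquinone synthesis gene ubiU (b3158) and yedE (b1929). The ansB gene, at 3093041 to 3094087 on the minus strand, fell from 8227 to 167 ± 9.62 (SD, n = 2), with a log2 fold change of -5.62 ± 0.74 (limma adjusted p = 0.00232). The plaP, uraA, ubiU and yedE genes fell 45.5-fold, 32.5-fold, 43.6-fold and 55.2-fold.

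The ciclopirox libraries differed from the control in a similar way, and replicate 1 lay farther from it. Across 4275 genes, which are not independent replicates, the log2 ratios of the ciclopirox libraries to the shared control had a Pearson correlation of 0.886 and a Spearman correlation of 0.855. Unchanged libraries simulated against the same control gave 0.487 and 0.470 over 100 simulations. The covariance was 3.66 against a simulated 0.523, a difference of 3.14. Fold changes given without a value per library pool ciclopirox libraries whose log2 ratios differed with an SD of 1.06. The SD of the log2 ratios was 2.25 in replicate 1 and 1.83 in replicate 2, and replicate 1 was farther from the control in 67.0% of genes. In both libraries 825 genes were at least 2-fold higher and 815 at least 2-fold lower, and 26 were at least 2-fold apart from the control in opposite directions. Replicate 1 alone gave 1250 higher and 1277 lower, and replicate 2 alone gave 1023 and 943. Among 95 called genes picked by the naming rule, 36 lost the call without the low-value filter and 17 without limma's trend. Every one of the 486 called genes was at least 2-fold changed in both libraries, and the smallest called change was 4.68-fold. The lone control was assumed to vary like the ciclopirox libraries, whose difference gave the 1 residual degree of freedom. With quantile normalisation no gene passed an adjusted p of 0.05 by limma (969 at an unadjusted p under 0.05), against 302 higher and 184 lower on the deposited scale, 422 and 326 by edgeR on recovered reads, and 744 and 679 by DESeq2.

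**Figure D1:**
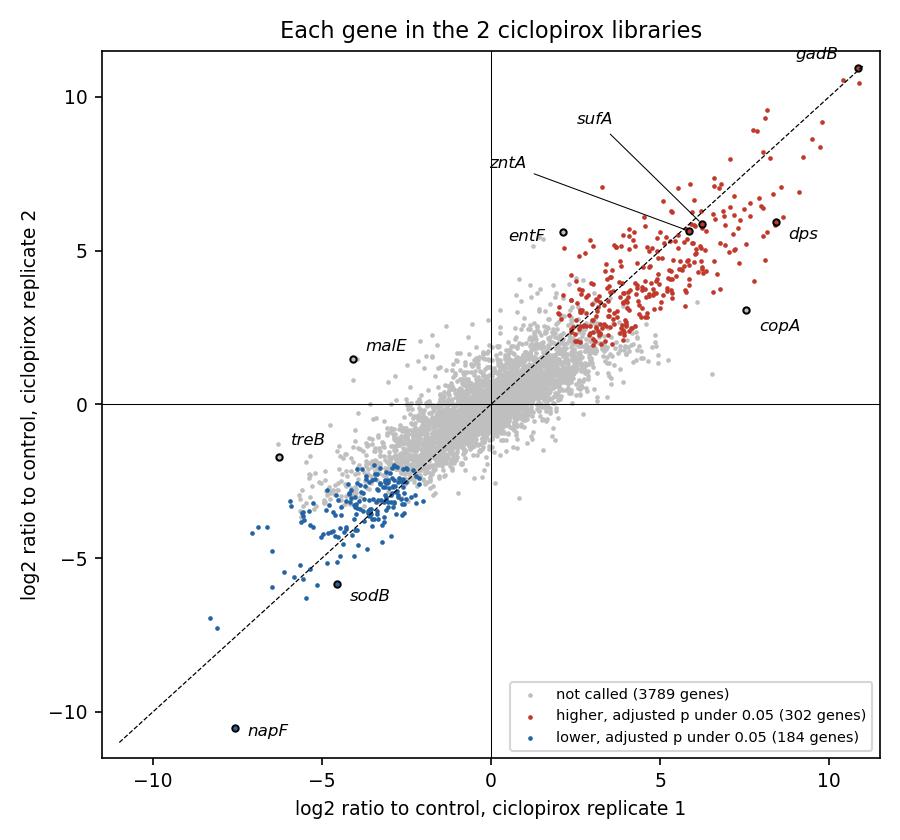
Log2 ratio to the control of each of 4275 genes in ciclopirox replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the 302 genes called higher in red, the 184 called lower in blue and a dashed line of equality. The gadB gene lies at the upper end near the line, napF at the lower end and off it, and malE, treB, entF and copA also differ between the ciclopirox libraries.

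Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, and 15 of the 41 lists passed an adjusted p of 0.05, 8 upward and 7 downward. With an estimated correlation none passed, and the adjusted p was 0.965 for each of the 41. That correlation and its test rest on 1 residual degree of freedom, and 0 of 4 simulated lists shifted 4-fold were called with it. The values with an estimated correlation given below therefore decide nothing about a list. The acid resistance list rose: 14 of its 18 genes were higher, 0 were lower and 4 were not called (camera adjusted p = 9.93e-12, and adjusted p = 0.965 with an estimated correlation). Adjusted over the list alone, 16 were higher and 1 was lower. Its median log2 fold change was 7.33. The 4 genes not called encode the arginine-dependent and lysine-dependent systems, namely adiA at 2.22, adiC at 1.54, cadA at -1.34 and cadB at -1.88 on the log2 scale. Examples among the genes that rose were gadB, gadC, gadA and slp, at 10.90, 10.66, 10.48 and 9.06.

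The general stress and stationary phase list was written around the sigma factor RpoS, though not every member need depend on it. The list rose with a median log2 fold change of 5.52 (camera adjusted p = 1.21e-15, and adjusted p = 0.965 with an estimated correlation). Of its 25 genes, 21 were higher, 0 lower and 4 not called, and adjusted over the list alone 23 were higher. The ribosome modulation factor gene rmf rose from 638 to 245020 and 85158, and the pyruvate oxidase gene poxB from 284 to 30517 and 37163. The stress gene yjbJ and the stationary-phase ribosome-associated gene sra rose 149-fold and 83.3-fold. The genes not called were bolA, raiA, hpf and cbpA, at 4.71, 1.27, 1.52 and 3.34 on the log2 scale. The DNA-protecting ferritin-like protein gene dps, also in the peroxide list, rose from 2589 to 888151 and 157281 by limma (adjusted p = 0.0285), but not by edgeR (adjusted p = 0.127, with a range of 5.74e-15 to 0.131 over 11 alternatives).

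All 6 genes of the Suf iron-sulfur cluster assembly list rose, also when adjusted over the list alone, with a median log2 fold change of 4.85 (camera adjusted p = 9.52e-06, and adjusted p = 0.965 with an estimated correlation). Of these, sufA and sufB rose from 96.7 to 6546 ± 1214 and from 513 to 20405 ± 297 (SD, n = 2). The sufC and sufS genes rose 26.3-fold and 30.3-fold. In the list of the housekeeping Isc system, 2 of 8 genes were lower, 0 higher and 6 not called, with the same 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.466). The 2 were iscX and the ferredoxin gene fdx, at -2.57 and -2.83 on the log2 scale, calls that held in 8 and 7 of 11 alternatives (limma adjusted p = 0.0392 and 0.0482, ranges 8.43e-06 to 0.131 and 9.53e-05 to 0.167). The regulator gene iscR, named after its values were seen, was at 2.70 (limma adjusted p = 0.113).

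The list of manganese import and the manganese-dependent ribonucleotide reductase rose, with 6 of 8 genes higher, 0 lower and 2 not called, and the same 6 counts adjusted over the list alone. Its median log2 fold change was 3.96 (camera adjusted p = 1.23e-04, and adjusted p = 0.965 with an estimated correlation). The reductase operon genes nrdH, nrdI and nrdE rose 77.6-fold, 57.8-fold and 21.2-fold, and the manganese importer gene mntH rose from 234 to 2519 and 3232. The genes not called were the regulator gene mntR and the manganese superoxide dismutase gene sodA, at 1.07 and 0.37 on the log2 scale.

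Iron acquisition genes were less uniform. The list of enterobactin synthesis, export and release had a median log2 fold change of 3.03 (median log2 ratios 1.33 in replicate 1 and 4.58 in replicate 2) and was called upward (camera adjusted p = 0.00376, and adjusted p = 0.965 with an estimated correlation). Only 1 of its 10 genes was called, ybdZ at 3.62 (limma adjusted p = 0.0492), with 0 lower, and adjusted over the list alone none was. By edgeR 8 of the 10 were called and by DESeq2 7. The ybdZ call held in 5 of 11 alternatives, with adjusted p from 1.42e-05 to 0.274. The synthetase gene entF stood at 777 in the control and at 3373 and 37663 with ciclopirox, the esterase gene fes at 254 against 909 and 3790, and entA at 159 against 463 and 6602. None of the 26 genes of the TonB-dependent receptor and siderophore import list was called by limma, either over all genes or adjusted over the list alone, with 7 of the 26 at an unadjusted p under 0.05, 1 called by edgeR and 10 by DESeq2. Its median was 0.24 and its mean 0.05 on the log2 scale while camera's direction was downward (adjusted p = 0.859), and the libraries differed in direction, with medians of -0.51 in replicate 1 and 0.96 in replicate 2. In both libraries 3 of the 26 were at least 2-fold higher and 6 at least 2-fold lower. The receptor genes fhuE and fepA were at 2.33 and 2.51, and fepG and fepD at 1.29 and 1.35.

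In the ferrous iron import list 1 of 6 genes was lower, 0 higher and 5 not called, with 2 lower when adjusted over the list alone (camera adjusted p = 0.119). That gene was feoA, which fell from 3060 to 96.2 and 165, beside feoB at -2.97 on the log2 scale. Among 13 genes for iron storage and iron-containing proteins known to be lowered by the small RNA RyhB, 2 were lower, 0 higher and 11 not called, also adjusted over the list alone (camera adjusted p = 0.834). In both libraries 4 of the 13 were at least 2-fold higher and 2 at least 2-fold lower. The iron superoxide dismutase gene sodB fell from 17221 to 737 and 295, and the ferritin gene ftnA from 2683 to 397 and 335. The succinate dehydrogenase gene sdhB and the aconitase gene acnB, which were not called, were at -1.40 and -1.22 on the log2 scale.

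**Figure D2:**
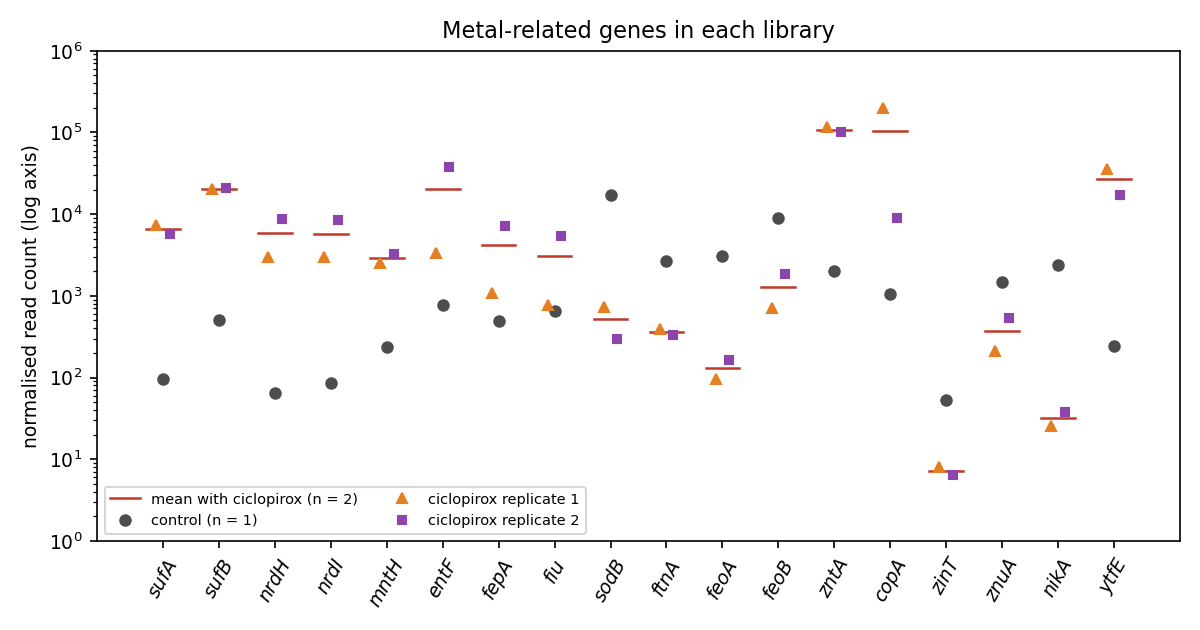
Normalised read count (log axis) of 18 metal-related genes in the control library and in each ciclopirox library, with a red bar at the ciclopirox mean (n = 2). The sufA, sufB and zntA values of both ciclopirox libraries lie close together above the control, sodB, ftnA and nikA lie below it, and copA, entF and fepA are spread apart.

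The zinc and copper homeostasis list, which also holds the nickel importer, had 1 of 25 genes higher, 5 lower and 19 not called, with 2 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.12). The nickel importer genes nikA, nikB, nikC and nikD fell, with log2 fold changes of -6.21, -4.19, -3.63 and -2.66, as did the zinc-binding protein gene zinT, at -2.74. The zinc and lead exporter gene zntA rose from 2013 to 116197 and 100304 by limma (adjusted p = 0.0261). It was not called by edgeR (adjusted p = 0.0976, with a range of 2.40e-12 to 0.118 over 11 alternatives). The copper exporter gene copA, named after its values were seen, stood at 1067 in the control and at 200360 and 8898 with ciclopirox, and was not called (limma adjusted p = 0.0745).

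The superoxide and nitric oxide response list was called upward, with 4 of 15 genes higher, 0 lower and 11 not called, and 5 higher adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.965 with an estimated correlation). Its median log2 fold change was 1.11. The iron-sulfur cluster repair gene ytfE rose from 244 to 36020 and 17333, and the flavohaemoglobin gene hmp, which detoxifies nitric oxide, from 1418 to 61532 and 55733. The regulator gene soxS and the fumarase gene fumC rose 9.64-fold and 12.2-fold. Neither hmp nor fumC was called by edgeR (adjusted p = 0.0765 and 0.0718, with ranges over 11 alternatives of 1.58e-10 to 0.116 and 1.45e-06 to 0.153). In the peroxide response list dps was the 1 gene of 10 that rose, 0 were lower and 9 were not called, also adjusted over the list alone. The catalase gene katG and the peroxidase gene ahpF were at -1.03 and -1.06 on the log2 scale. The list's median was -0.13 (-0.82 in replicate 1 and 0.09 in replicate 2) while its mean was 0.73 and camera's direction upward (adjusted p = 0.743).

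All 54 ribosomal protein genes were at least 2-fold lower in both ciclopirox libraries, and their median log2 fold change was -3.71 (camera adjusted p = 3.85e-16, and adjusted p = 0.965 with an estimated correlation). Over all genes tested 7 of the 54 were called lower and 0 higher, and adjusted over the list alone 51 were lower. The rpsJ, rplD and rplW genes fell, with log2 fold changes of -4.61, -4.57 and -4.54. The rplC gene stood at 146049 in the control and at 2976 and 11440 with ciclopirox (limma adjusted p = 0.0554). The list's median log2 ratio was -4.51 in replicate 1 and -2.90 in replicate 2.

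The ATP synthase list had a median log2 fold change of -3.68 (camera adjusted p = 0.00124, and adjusted p = 0.965 with an estimated correlation). None of its 9 genes was called by limma over all genes tested, while 4 were lower adjusted over the list alone, 6 were at an unadjusted p under 0.05, 0 were called by edgeR and 5 by DESeq2. Its median log2 ratio was -5.36 in replicate 1 and -2.25 in replicate 2, and the example atpH stood at 30215 in the control against 714 and 5711. The NADH dehydrogenase I list had a median of -2.70, or -3.36 in replicate 1 and -1.95 in replicate 2 (camera adjusted p = 8.45e-05, and adjusted p = 0.965 with an estimated correlation), with 0 of 13 genes called by limma and 6 lower adjusted over the list alone. Of those 13, 9 were at an unadjusted p under 0.05, 5 were called by edgeR and 12 by DESeq2. The nuoH and nuoM genes were at -3.09 and -3.23 on the log2 scale. In the terminal oxidase list the bd-II oxidase genes appC and appB rose 36.5-fold and 21.0-fold, and 0 of the 10 were called lower, with the same counts adjusted over the list alone. By size, 2 of the 10 were at least 2-fold higher and 5 at least 2-fold lower in both ciclopirox libraries. The cytochrome bo oxidase genes cyoB and cyoC, not called, were at -3.08 and -3.03, and the list was not called (camera adjusted p = 0.743).

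The list of anaerobic respiration and hydrogenases was called downward, with 15 of 53 genes lower, 3 higher and 35 not called, and 17 lower and 7 higher adjusted over the list alone. Its median log2 fold change was -0.87 (camera adjusted p = 7.75e-04, and adjusted p = 0.965 with an estimated correlation). Besides napF, napD and nirB, the periplasmic nitrate reductase gene napA fell from 3141 to 141 and 103. The 3 genes that rose, hyaC, hyaD and hyaE, belong to hydrogenase 1, and they rose 6.07-fold, 6.80-fold and 5.91-fold. Their calls held in 7, 7 and 8 of 11 alternatives (limma adjusted p = 0.045, 0.0439 and 0.0413, ranges 0.00171 to 0.185, 4.42e-04 to 0.217 and 0.00243 to 0.162).

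The flagella and chemotaxis list was lower, with 21 of 47 genes lower, 0 higher and 26 not called, and 29 lower adjusted over the list alone. The median of its log2 fold changes was -2.09 (camera adjusted p = 6.87e-12, and adjusted p = 0.965 with an estimated correlation). The basal body and rod genes flgB, flgC, fliF and fliL fell from 867, 770, 614 and 489 to 5.42, 5.42, 37.9 and 19.0 in replicate 1 and to 46.6, 47.6, 34.9 and 24.4 in replicate 2. The flagellin gene fliC, named after its values were seen, was not called, at -0.94 on the log2 scale. In the curli and type 1 fimbriae list 3 of 16 genes were lower, 0 higher and 13 not called, with 4 lower adjusted over the list alone (camera adjusted p = 0.188). Those 3 were fimC, fimB and fimD, of type 1 fimbriae, which fell 10.3-fold, 11.8-fold and 4.88-fold. The fimD call held in 7 of 11 alternatives (limma adjusted p = 0.0458, range 2.12e-04 to 0.131).

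The purine and pyrimidine synthesis list was lower, with 8 of 25 genes lower, 0 higher and 17 not called, and 17 lower adjusted over the list alone. Its median log2 fold change was -2.36 (camera adjusted p = 3.13e-10, and adjusted p = 0.965 with an estimated correlation). The dihydroorotate dehydrogenase gene pyrD fell from 1062 to 69.1 and 43.4, and codB, purK and guaB fell, with log2 fold changes of -3.43, -3.11 and -3.53. The list of lipopolysaccharide core and lipid A synthesis was also called downward, with a median of -1.08, or -1.53 in replicate 1 and -0.42 in replicate 2 (camera adjusted p = 0.00816, and adjusted p = 0.965 with an estimated correlation). Of its 29 genes 1 was lower, lpxH at -2.60, 0 were higher and 28 not called, and adjusted over the list alone none was called. The lpxA and waaL genes were at -1.87 and -2.28.

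**Figure D3:**
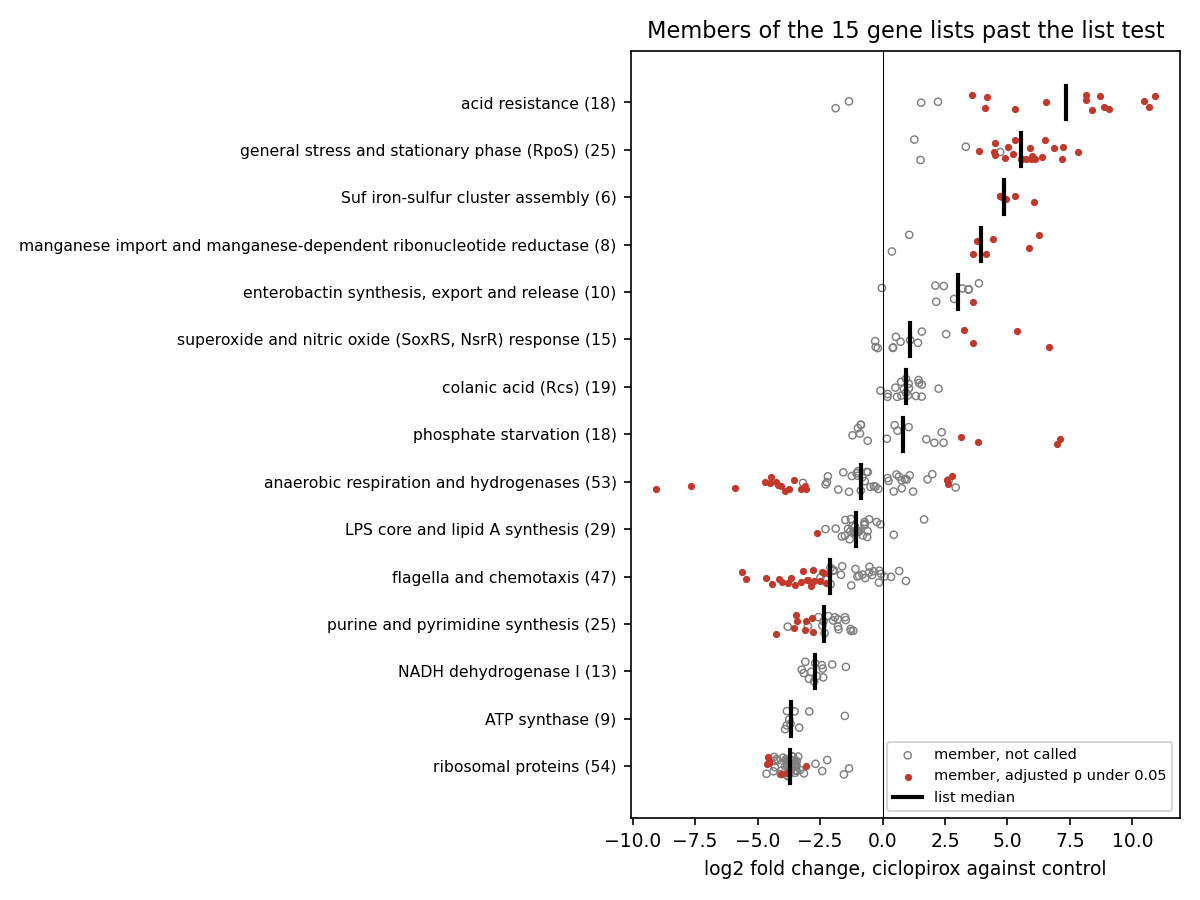
Log2 fold change of each member of the 15 lists past the camera test, with list size in brackets, filled red points for genes at an adjusted p under 0.05 and a black bar at the list median. Medians run from -3.71 for ribosomal proteins to 7.33 for acid resistance, and the colanic acid, NADH dehydrogenase I and ATP synthase lists hold no called gene.

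The phosphate starvation list was called upward, with 4 of 18 genes higher, 0 lower and 14 not called, and 6 higher adjusted over the list alone. The list's median log2 fold change was 0.82 (camera adjusted p = 0.0378, and adjusted p = 0.965 with an estimated correlation). The call ended with quantile normalisation and with a minimum mean of 10 (adjusted p = 0.0541 and 0.0532, range 0.0205 to 0.0541 over 9 alternatives). The genes that rose were phoH and the glycerol-3-phosphate transporter genes ugpB, ugpA and ugpE, at 7.12, 6.99, 3.84 and 3.13 on the log2 scale, with phoH at 8.40 and 5.83 in the libraries. The phosphate transporter and alkaline phosphatase genes pstS and phoA, named after their values were seen, were at -0.59 and -0.99 and not called. The colanic acid list was called upward with a median of 0.94 (camera adjusted p = 0.0149, and adjusted p = 0.965 with an estimated correlation), although none of its 19 genes was called by limma, also adjusted over the list alone. Of those 19, 3 were at an unadjusted p under 0.05, 1 was called by edgeR and 1 by DESeq2. The colanic acid list call ended with total-count scaling and with edgeR's scaling (adjusted p = 0.0714 and 0.0873, range 0.00624 to 0.0873 over 9 alternatives). The wcaI and cpsB genes were at 2.24 and 1.44.

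Genes of other stress responses mostly passed no test. None of the 18 heat shock genes was called by limma, also adjusted over the list alone, with the chaperone genes clpB and dnaK at 2.58 and 1.78 on the log2 scale (camera adjusted p = 0.689). Of the 18, 0 were at an unadjusted p under 0.05, 1 was called by edgeR and 3 by DESeq2. None of the 22 SOS genes was called by limma, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, 0 called by edgeR and 4 by DESeq2. The SOS list's median was -0.09 and its mean 0.09 with an upward camera direction (adjusted p = 0.9), and dinI and lexA were at -1.66 and -0.76. In the envelope stress list the chaperone gene spy rose 7.28-fold, 0 of 16 genes were lower, 15 were not called and adjusted over the list alone none was called (camera adjusted p = 0.741). The rpoE gene was at 2.56. The phage shock list had a median of 2.49 (3.81 in replicate 1 and 1.29 in replicate 2) with 0 of 7 genes called by limma and 3 higher adjusted over the list alone (camera adjusted p = 0.0743), and pspD and pspC were at 2.90 and 2.81. Of the 7, 4 were at an unadjusted p under 0.05, 4 were called by edgeR and 5 by DESeq2. The phage shock list was called with total-count scaling and with edgeR's scaling (adjusted p = 0.0365 and 0.0361, range 0.0361 to 0.177 over 9 alternatives). In the Mar regulon and drug efflux list the mdtE and mdtF genes, which lie next to gadE, rose, with log2 ratios of 4.51 and 6.10 for mdtE and 3.02 and 5.16 for mdtF, 0 of 21 genes were lower and 19 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.743). The porin gene ompF was at -4.57 and not called (limma adjusted p = 0.0767).

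Amino acid synthesis lists were not called. In the branched-chain list ilvC, ilvN and ilvM fell, with log2 fold changes of -4.18, -3.17 and -2.69, 0 of 17 genes were higher and 14 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.333). The ilvM gene had 46 reads in the control against 4 and 3, and its call held in 7 of 11 alternatives (limma adjusted p = 0.044, range 0.0121 to 0.107). In the methionine list the cobalamin-independent methionine synthase gene metE rose from 506 to 20221 and 39873, and mmuP rose 4.93-fold, a call that held in 6 of 11 alternatives (limma adjusted p = 0.0489, range 3.35e-04 to 0.188). The other 13 of 15 genes were not called, 0 were lower, and the counts were the same adjusted over the list alone. That list's median was -0.24 while its mean was 0.44 and camera's direction upward (adjusted p = 0.741), and the libraries differed in direction, with medians of -0.81 and 0.36. In the arginine synthesis list carA, which also serves pyrimidine synthesis, fell by 2.79 and the other 11 of 12 genes were not called, also adjusted over the list alone. Its median was 0.31 while its mean was -0.11 and camera's direction downward (adjusted p = 0.859). By limma none of the 22 aromatic, tryptophan and histidine synthesis genes and none of the 23 cysteine and sulfate assimilation genes was called, also adjusted over each list alone (camera adjusted p = 0.689 and 0.729). At an unadjusted p under 0.05 there were 2 and 3 of them, edgeR called 0 and 2, and DESeq2 called 4 and 3. The aroA gene was at -2.04, and the sulfite reductase genes cysI and cysJ were at -2.27 and -2.20.

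Lists of carbon use were not called either, though camera asks only for a shift one way. The fatty acid list moved both ways, with 7 of 22 genes at least 2-fold higher and 11 at least 2-fold lower in both ciclopirox libraries. In the fatty acid list the degradation genes fadA, fadB and fadE rose 10.7-fold, 17.9-fold and 34.5-fold and the synthesis gene accC fell 14.8-fold, with 18 of 22 genes not called and 7 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.741). In the glycolysis list the stationary-phase aldolase gene fbaB rose 39.6-fold and the other 16 of 17 genes were not called, also adjusted over the list alone (camera adjusted p = 0.741). The TCA cycle list had fumC as its 1 called gene of 14, with 0 lower and none called adjusted over the list alone (camera adjusted p = 0.743), and sucB and sucD were at -2.02 and -1.94 on the log2 scale. In the list of tryptophan, serine, threonine and sugar-alcohol catabolism the serine dehydratase gene sdaB, the serine transporter gene sdaC and the regulator gene tdcA fell, with log2 fold changes of -4.51, -3.66 and -4.42, 0 of 23 genes were higher and 20 were not called, also adjusted over the list alone (camera adjusted p = 0.729). The list's median was -1.14 in replicate 1 and above 0 in replicate 2. In the maltose, glycerol, trehalose and ribose list the glycerol-3-phosphate dehydrogenase gene glpD rose from 300 to 9664 and 2643, the other 24 of 25 genes were not called and adjusted over the list alone none was. Its median was 0.19 while its mean was -0.21 and camera's direction downward (adjusted p = 0.9), and the libraries differed in direction, with medians of -0.90 and 0.65. By limma none of the 11 fermentation genes and none of the 12 galactose genes was called, also adjusted over each list alone (camera adjusted p = 0.466 and 0.743). At an unadjusted p under 0.05 there were 1 and 0 of them, edgeR called 0 and 0, and DESeq2 called 2 and 0. The focA gene was at -2.09.

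Of the 7 genes in the list of those deleted in the parent genotype of BW25113, araD, rhaD and lacZ were in the authors' table. The lacZ entry there ran from 358942 to 360066 on the minus strand, so its reads were assigned to a stretch that the authors' annotation holds. Reads of this entry therefore need not come from a deleted sequence. The control held 17, 7 and 24 reads of them. The normalised lacZ value rose from 16.9 to 186 and 73.0 (limma adjusted p = 0.0391), 0 were lower and 2 were not called, also adjusted over the list alone. The list's median was -0.14 (-0.74 in replicate 1 and 0.46 in replicate 2) while its mean was 0.65 and camera's direction upward (adjusted p = 0.741).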

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

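Total-count scaling, edgeR and DESeq2 were chosen after seeing the data. No direction of a named gene or called list reversed. Against 302 higher and 184 lower genes, quantile normalisation gave 0 and 0 by limma (969 at an unadjusted p under 0.05; edgeR and DESeq2 counts follow), no low-value filter 167 and 85, total-count scaling 552 and 292, and DESeq2 744 and 679. edgeR gave 422 and 326, and robust limma 383 and 288. With 1 residual degree of freedom the limma counts moved with its prior degrees of freedom, which were 9.03 in the reported fit, 2.94 after quantile normalisation, 4.78 without the filter, 17.0 with robust moderation and 181 with total-count scaling. Total-count scaling moved the median log2 fold change of all genes to 0.27 and quantile normalisation to -0.13. Of the calls in the reported fit, 252 were shared without the filter and 478 with edgeR. The 24 named genes kept their call in every alternative with a test except quantile normalisation, where all 24 lost it. Among 190 genes, picked by the naming rule with copA added, 95 calls were lost with quantile normalisation, 36 without the filter, 17 without the trend and 4 with edgeR. With a ciclopirox replicate left out there was no test, and the count of genes at least 2-fold higher ranged from 1023 to 1250 against 825, and of those at least 2-fold lower from 943 to 1277 against 815, since only 1 library then had to pass. The number of lists called stayed between 14 and 15. The curli and type 1 fimbriae list was called with a minimum mean of 10 (adjusted p = 0.0264, range 0.0264 to 0.326). The replicate correlation, computed again only without the filter and with a minimum mean of 10, was 0.886 and 0.890. Median-ratio rescaling changed no call because the deposited values already have that scale, so it shows nothing about stability. It is nevertheless 1 of the 11 alternatives counted for each gene and of the 9 counted for each list. Every count of alternatives in which a call held therefore includes it. No paired analysis was possible because the only control library shares at most 1 replicate number with the ciclopirox libraries. Apart from edgeR and DESeq2, alternatives written for raw counts, such as limma-voom, were not run. The 3 libraries allow 3 choices of a lone library, too few for a share under 0.05. With a ciclopirox library as the lone one, the residual spread holds the difference between control and ciclopirox itself. Few calls were then bound to follow, so comparing these choices decides nothing about the reported calls. At these depths limma recovered 8% of simulated 4-fold changes, so smaller changes were mostly not detectable.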

Other observations

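The lists and the category test in this paragraph and the next were written after the gene table had been seen, so they describe these libraries and are not independent tests. All 5 genes of the arginine succinyltransferase pathway rose, with a median log2 fold change of 6.76 (camera adjusted p = 2.80e-06, and adjusted p = 0.717 with an estimated correlation). Besides astA and astC, the astB, astD and astE genes rose from 34.6, 38.1 and 17.6 to 9793, 10396 and 4126 in ciclopirox replicate 1 and to 915, 1722 and 296 in replicate 2. All 6 genes for the use of glutarate and gamma-aminobutyrate rose, with a median of 5.91 (camera adjusted p = 9.14e-07, and adjusted p = 0.717 with an estimated correlation). The glaH and lhgD genes of glutarate use were at 8.33 and 7.53, and gabD, gabT and gabP, which the general stress list also holds, were at 6.09, 5.74 and 4.92. In a list of 18 nitrogen limitation genes only argT rose, at 3.85 on the log2 scale, 17 were not called, and glnA was at -3.75 (limma adjusted p = 0.0554).

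The translation factor list had a median log2 fold change of -2.79 with 3 of 13 genes lower and 0 higher (camera adjusted p = 1.68e-04, and adjusted p = 0.717 with an estimated correlation), the 3 being infA, prfA and prfC. The aminoacyl-tRNA synthetase list had a median of -1.98 with 1 of 23 genes lower, cysS, and 0 higher (camera adjusted p = 1.36e-04, and adjusted p = 0.717 with an estimated correlation). The lysU gene for the inducible lysyl-tRNA synthetase stood at 12809 in the control and at 14896 and 33188 with ciclopirox, against 22559, 1931 and 3840 for its counterpart lysS, neither of them called. In the Sec translocase and outer membrane assembly list 1 of 13 genes was lower, yidC at -4.01 (camera adjusted p = 0.0191, and adjusted p = 0.717 with an estimated correlation). In the list of the DLP12 prophage region 4 of 18 genes were lower and 0 higher, namely borD, rzpD, ybcW and the outer membrane protease gene ompT, which fell from 32061 to 526 and 3242 (camera adjusted p = 0.00681, and adjusted p = 0.717 with an estimated correlation). The other 8 lists of this kind were not called. Among the gene categories in the authors' table, those for translation, motility, nucleotide and coenzyme metabolism were called downward by camera, with medians of -2.21, -2.46, -1.25 and -0.56 (adjusted p = 1.33e-12, 9.11e-12, 6.20e-05 and 0.0204). Secondary metabolism was called upward with a median of 0.93 (adjusted p = 0.0459). With an estimated correlation none of these was called (adjusted p = 0.802 for each).

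Several genes differed more than 10-fold between the ciclopirox libraries, as quotients of the normalised values. The maltose genes malE and malK were 47.6-fold and 44.1-fold higher in replicate 2, where malE stood at 24789 against 520 in replicate 1 and 8925 in the control. The trehalose genes treB and treC were 23.5-fold and 32.3-fold higher in replicate 2, and entB, entH and entA were 16.5-fold, 14.9-fold and 14.2-fold higher there. In replicate 1 bhsA was 46.8-fold and copA 22.5-fold higher than in replicate 2.

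Of the tests that follow, those of control RNA in replicate 2, of a few abundant genes, of zinc excess and of the authors' scaling were chosen after the result was seen. Ciclopirox replicate 1 lay farther from the control than replicate 2, with an SD of log2 ratios 1.23 times as large. Sequencing depth is argued against, since with all libraries thinned to 8958322 reads the ratio of SDs over 4073 genes was 1.225, against 1.233 before. The 95% interval of 1.203 to 1.249, like that of the next test, came from 1000 resamples of genes. Genes are not independent replicates, so both intervals are too narrow and leave out the spread between libraries. Control RNA mixed into replicate 2 was bounded by genes that were nearly absent there: 20 genes with at least 1000 normalised reads in the control stood under 5% of it, and taking out the share of 2.73% that the 10th lowest gene allows left a ratio of 1.135 (1.1 to 1.171). This test replaced an earlier one that decided nothing. The lower end of its interval only reaches the limit of 1.1 set for it, and a wider interval would cross that limit. The share taken out is generous, since sodB at 1.71% and napF at 0.0347% of the control allow less. By those values, and not by the interval, control RNA is argued against as the whole cause. A biological difference was not tested and stays open, and the labels do not say whether the ciclopirox libraries came from separate cultures or from 1.

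The metal exporter genes copA and zntA were higher with ciclopirox in both treated libraries, although copA did not pass the test. That a few genes took most of the counts is argued against, since the smallest of the per-library log2 ratios was 2.96 under total-count, trimmed-mean and quantile scaling. For copper-sensing regulators being active, the median log2 ratio of cueO, cusC, cusF, cusB and cusA was 0.19 in replicate 1 and -0.030 in replicate 2, with members on both sides of 0. That value lies just past the limit of 0 written beforehand, at which the explanation was to be excluded. A margin for the members' spread was added after it was seen, so the explanation is left undecided. Apart from cueO, at 0.19 and 0.048 in replicates 1 and 2, the set holds only cus genes. The copper regulator gene cueR, outside the set and named after its values were seen, was at 2.84 and 1.76. Zinc excess sensed by Zur was undecided as well, since the median of its targets was -1.43 in replicate 1 and -0.66 in replicate 2, short of the -1 it needed in both.

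The ribosomal protein list was called downward with a preset correlation (7 of 54 genes lower over all genes tested) and not with an estimated one (adjusted p = 0.965). The latter test could not decide with 1 residual degree of freedom. The authors' scaling is argued against by the highest per-library median of -2.58 under total-count, trimmed-mean and quantile scaling. Gene length is argued against by 1560 other genes of 172 to 712 bp, whose median log2 fold change was 0.072. Slower growth or a later growth phase with ciclopirox is a candidate explanation: the median log2 ratio of the ribosome-inactivation and stationary-phase genes rmf, hpf, sra, yqjD and elaB was 5.17 in replicate 1 and 5.45 in replicate 2, where a cause of this kind needed at least 1. All samples were taken at the same optical density, 4 of those 5 genes also sit in the general stress list, and growth rates are not given in the labels, so a direct drug effect on these genes stays open and untested.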
